A study of Rattus norvegicus with 18 samples.

How the data were processed

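Kidney RNA from male rats aged 23 weeks was sequenced in 18 libraries, 3 in each of 6 groups, and each library's group and replicate number were taken from its label. Libraries were prepared from 1 µg of RNA with the NEBNext Ultra RNA kit for Illumina, per the labels' protocols, a kit that does not mark strand. The submitters' processing notes name CASAVA 1.7, Bowtie 0.12.2 and the genome build mm8 without saying what each was used for. A mouse build such as mm8 cannot be the source of the rat Ensembl identifiers and positions in the table. The rat build, the annotation release, the read counter and its strand setting are not given in the sources used here, and positions are printed as deposited.

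The deposited values are whole-number counts per feature, although the table is titled as FPKM. All 522 values were whole. Read as FPKM, they would assign between 5.88 and 12.1 times the reads of a library to the listed features, which cannot exceed 1. The unit of counts is therefore a reading of the values and not a statement of the authors. The table analysed here holds 29 features in descending order of their total over the libraries: 12 mitochondrial genes, 16 nuclear genes and 1 unnamed feature. Library depth is therefore unknown, and the totals of the listed features, from 4440262 to 10306858, are not depths. The listed counts lay between 10521 and 3382727, so counting error is small beside the spread between libraries. The 95% Wilson intervals given for shares cover counting error only.

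Because the values were counts, differences were tested with edgeR 4.0.16 (quasi-likelihood F test, 1 fit over all 18 libraries, or the 12 diabetic ones for the dose slope, with no dispersion trend and no filter) in R 4.3.3. The plan fixed before the data were examined had named limma on log2(FPKM + 1) under the belief that the values were FPKM; limma 3.58.1 on log2(scaled count + 1) was kept as an alternative. P-values were adjusted over the 29 features of a comparison by the Benjamini-Hochberg method, with a threshold of 0.05. All model tests were two-sided, and the SE of a log2 fold change was its size divided by the square root of F. The planned comparisons were DM with NC, each flour dose with DM, the 3 doses together with DM, a slope of log2 count over dose in g per kg among the diabetic groups, NH with NC, and the difference between the high-dose effects in diabetic and healthy rats. The dose of NH in g per kg is not given by its own label, so NH was left out of the slope. A comparison of HP with the mean of LP and MP, and one of all 12 diabetic with all 6 healthy libraries, were added after the data were seen.

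Scaling decides much of what such a short list shows, because the mitochondrial genes took between 77.1 and 95.5% of the counts of the 28 named genes. Trimmed mean of M-values (TMM) scaling over the 29 features was the main setting. It was set beside 3 others in the same edgeR test: median-of-ratios factors, the geometric mean of the 16 nuclear genes as the library size, and unscaled counts. DESeq2 1.42.0 was run as well. A call is described as held under all 4 scalings when it passed the threshold in the same direction in each of them, and folds are then given as the range over the scalings. The ratio of summed mitochondrial to summed nuclear counts does not depend on any scaling and was compared on the log2 scale with two-sided exact permutation tests. With 3 libraries against 3 the smallest such p is 0.1.

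The edgeR step was tested on simulated data for DM against NC, with counts of the 29 features drawn 200 times and 6 features changed in each draw. It recovered 85.2% of the features changed by 1.5-fold and 99.2% of those changed by 2-fold, and called 1.33% and 1.3% of the unchanged ones. When all 12 mitochondrial genes were halved in simulated DM libraries and nothing else was changed, TMM led to a mean of 15.5 of the 16 nuclear genes being called higher. The mean was 6.02 with median-of-ratios factors, 0.195 with nuclear scaling and 0.22 at the true library sizes.

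Replicate libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom between 104 and 3660 over the 18 pairs, so each counted as a separate sample. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples. No batch is recorded in the labels. In 2 pairs of groups, libraries with the same replicate number deviated together from their group means with r over 0.1 for all 3 numbers. These were DM and MP (r = 0.684, 0.465 and 0.733 for replicates 1 to 3) and MP and HP (r = 0.881, 0.807 and 0.149). Replicate 1 of NC, NH, DM, MP and HP also deviated together in every pairing (r from 0.438 to 0.897). LP replicate 1 went the other way against each of them (r from -0.749 to -0.461). This is a hint from the data and not from the labels, and its source was not tested. Over all pairs of groups, 21 of 45 same-numbered pairs had r over 0.1 (median 0.0765, and -0.0644 for unlike numbers). The main fit has no block for the number, and a fit with that block was run as an alternative. Gene lists for 24 pathways and cell types were fixed before the data were examined. Of these, 6 had a measured member and 18 had none. With 29 features there is no background for a list test, so members are counted only. Some listed genes, and the counts of the lists they belong to, are not reported here, although all 29 features entered the tests, the adjustment and the counts of calls. Under the rule fixed beforehand for naming genes, any gene could be named because the table held fewer than 60, with those past the threshold first.

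Some of the listed mitochondrial genes share bases in the deposited positions. ND4L (9870 to 10166) overlaps ND4 (10160 to 11537), ATP6 and COX3 share base 8599, and ND5 on the plus strand (11736 to 13565) overlaps ND6 on the minus strand (13543 to 14061). Counts of these genes are uncertain to the extent that reads were shared, and reads of ND5 and ND6 in the overlap cannot be told apart without strand. The alternatives tried were the scalings, DESeq2, limma with pseudocounts of 1 and 0.1, fits restricted to the groups compared, a slope over the rank of the dose, the replicate number as a block, and leaving out each library in turn. Planned filters on low FPKM, a per-million scale, quantile normalization and list tests did not apply to 29 counted features and were not run. Figures were drawn with matplotlib 3.10.9.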

Results

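Kidney RNA was measured in healthy rats given water (NC) or a high dose of plantain flour (NH) and in diabetic rats given water (DM) or flour at 1 (LP), 2 (MP) or 4 (HP) g per kg body weight, with 3 libraries in each group. Plantain flour was the treatment, and the series asks how it bears on the kidney transcripts of diabetic rats. Deposited counts were analysed for 12 mitochondrial genes, 16 nuclear genes and 1 unnamed feature. The listed counts of a library summed to 8884147 ± 298026 in NC, 9436890 ± 865340 in NH, 4769829 ± 288421 in DM, 4859682 ± 366292 in LP, 6080563 ± 464681 in MP and 6286297 ± 1109203 in HP (SD, n = 3). These sums cover the listed features and not the whole library.

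Among the listed genes, diabetic kidneys had a smaller share of mitochondrial counts than healthy kidneys. The list is ordered by totals over 18 libraries, 12 of them diabetic. If it was cut by that total, nuclear genes high in diabetic libraries were favoured, and the bearing of this on the share was not tested. The 12 mitochondrial genes, which encode subunits of the respiratory chain and of ATP synthase, made up 93.02% ± 0.32 of the counts of the 28 named genes in NC and 82.77% ± 0.711 in DM (SD, n = 3). The mitochondrial to nuclear ratio was 13.34 ± 0.6445 in NC and 4.809 ± 0.236 in DM, 2.77 times lower (log2 difference -1.47, SE 0.058, exact permutation p = 0.1, the smallest that 3 against 3 libraries allow, adjusted p = 0.14 over 7 ratio tests). In deposited counts, the mitochondrial sum was 8164353 ± 243761 in NC and 3914815 ± 268791 in DM, while the nuclear sum was 613629 ± 47931 and 813554 ± 22778. Over all feeds, the shares of the 12 diabetic libraries (77.1 to 88.7%) lay below those of the 6 healthy libraries (92.7 to 95.5%), a log2 difference in the ratio of -1.78 (exact permutation p = 5.387e-05, the smallest that the 18564 splits allow, adjusted p = 0.000377). This comparison was added after the data were seen and joins groups given different feeds, so its p-value is descriptive. Counting error was far smaller than these differences, with a 95% Wilson interval of 93.248 to 93.281% in NC replicate 1.

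Among diabetic rats, the mean mitochondrial share varied between doses. No exact permutation test of the ratio in 1 dose against DM could pass, since 3 against 3 libraries allow no p under 0.1. The share was 77.71% ± 0.869 in LP, 81.06% ± 1.56 in MP and 86.42% ± 2 in HP, against 82.77% in DM. The ratio was 1.38 times lower in LP than in DM (log2 -0.46, SE 0.059) and 1.33 times higher in HP (0.42, SE 0.15), with no overlap between libraries in either case (exact permutation p = 0.1 for each, adjusted p = 0.14). MP overlapped DM (log2 -0.16, SE 0.093, exact permutation p = 0.2), and its sign turned positive, to 0.18, without Gpx3 and Pck1. In LP the difference shrank to -0.15 without these genes. The HP difference was 0.27 without HP replicate 1, whose share of 88.7% was above the 85.8 and 84.8% of the other HP libraries. The 9 flour-fed diabetic libraries together did not differ detectably from DM (log2 -0.07, exact permutation p = 0.786). Healthy rats given flour had a higher share (94.95% ± 0.572 in NH) and ratio (log2 0.50, SE 0.11, exact permutation p = 0.1) than NC.

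**Figure D1:**
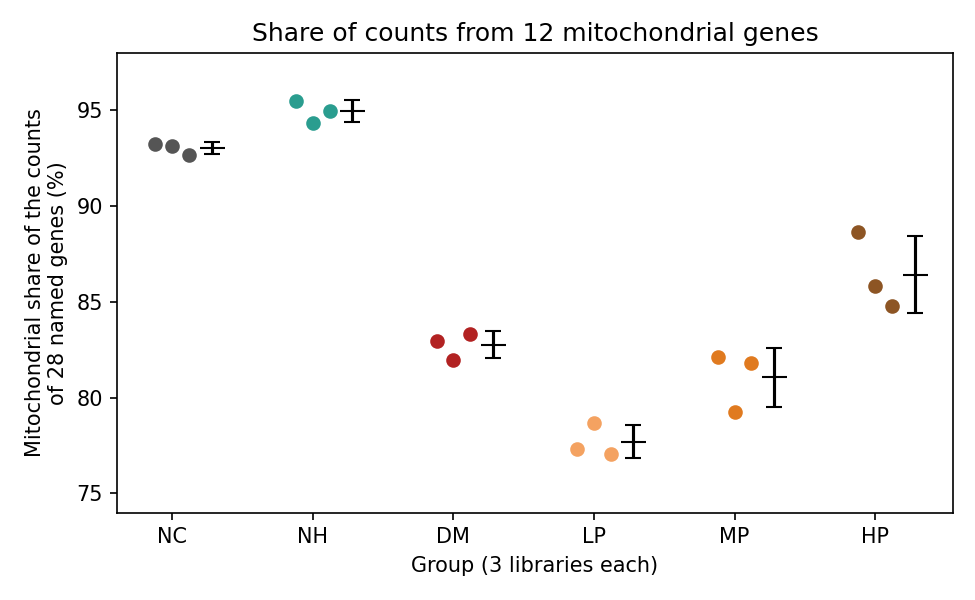
Share of the 12 mitochondrial genes in the counts of the 28 named genes (y axis, %, not starting at 0) by group (x axis). Dots are libraries and the bars beside them the mean ± SD of 3 libraries; the healthy groups NC and NH lie above 92% and the diabetic groups DM, LP, MP and HP between 77.1 and 88.7%.

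Comparing DM with NC asked which of the listed genes differed in untreated diabetic kidneys. Atp1b1, a beta subunit of the sodium pump, was higher in DM, at 62934 ± 2002 counts against 21009 ± 1286 in NC (SD, n = 3). Pck1, the rate-limiting enzyme of gluconeogenesis, was at 67806 ± 1891 counts against 21651 ± 2278. Gpx3, the secreted glutathione peroxidase, was at 101885 ± 2944 against 57869 ± 4365, and Cyp2c23, an arachidonic acid epoxygenase of the rat kidney, at 29391 ± 1335 against 15082 ± 780. These 4 genes were higher under all 4 scalings. Their folds ranged from 2.2 to 5.71 for Atp1b1, 2.31 to 5.98 for Pck1, 1.3 to 3.36 for Gpx3 and 1.43 to 3.71 for Cyp2c23 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p of at most 0.00077). The mitochondrial genes COX2 and ND2 were lower under all 4 scalings, by 1.31 to 3.41 times for COX2 and 1.21 to 3.14 times for ND2, although ND2 lost its call without NC replicate 2 or DM replicate 2. Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, had 38215 ± 1793 counts in DM against 80198 ± 4145 in NC. It was lower under 3 scalings and not under TMM (log2 -0.14, SE 0.080, adjusted p = 0.141 by edgeR).

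The phosphate transporter Slc34a1 was higher in DM under TMM and did not pass with nuclear scaling (log2 0.09). Of the antioxidant genes of the fixed lists, Gpx3 rose and Gclc did not pass under TMM, and the count adjusted over the list alone was also 1 of 2. The fatty acid omega-hydroxylase Cyp4a2 rose under TMM, likewise when adjusted over the list alone, and its log2 value was 0.06 with nuclear scaling. Miox, the oxygenase of myo-inositol, rose under TMM and turned to -0.41 with nuclear scaling. Among 10 respiratory chain genes, 2 fell under TMM (COX2, ND2), 1 rose (Atp5f1b, the beta subunit of ATP synthase, 0.05 with nuclear scaling) and 7 did not pass, with 3 passing when adjusted over the list alone. Under each of the other 3 scalings, all 9 mitochondrial members of the list fell.

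Counts of changed features depended on the scaling. TMM gave 16 changed features (14 higher and 2 lower), median-of-ratios factors 27 (13 and 14), nuclear scaling 24 (5 and 19) and unscaled counts 26 (10 and 16). The median log2 fold change of all 29 features moved with it, from 0.10 under TMM to -0.31, -1.28 and -0.84. Between DM and NC, 22 of 29 features had libraries that did not overlap on the TMM scale, where chance gives 10% for a single feature. The features share the TMM factors and are not independent, so this number cannot be read as that many separate changes. In the simulation with only the mitochondrial genes halved, TMM led to a mean of 15.5 of the 16 nuclear genes being called higher.

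**Figure D2:**
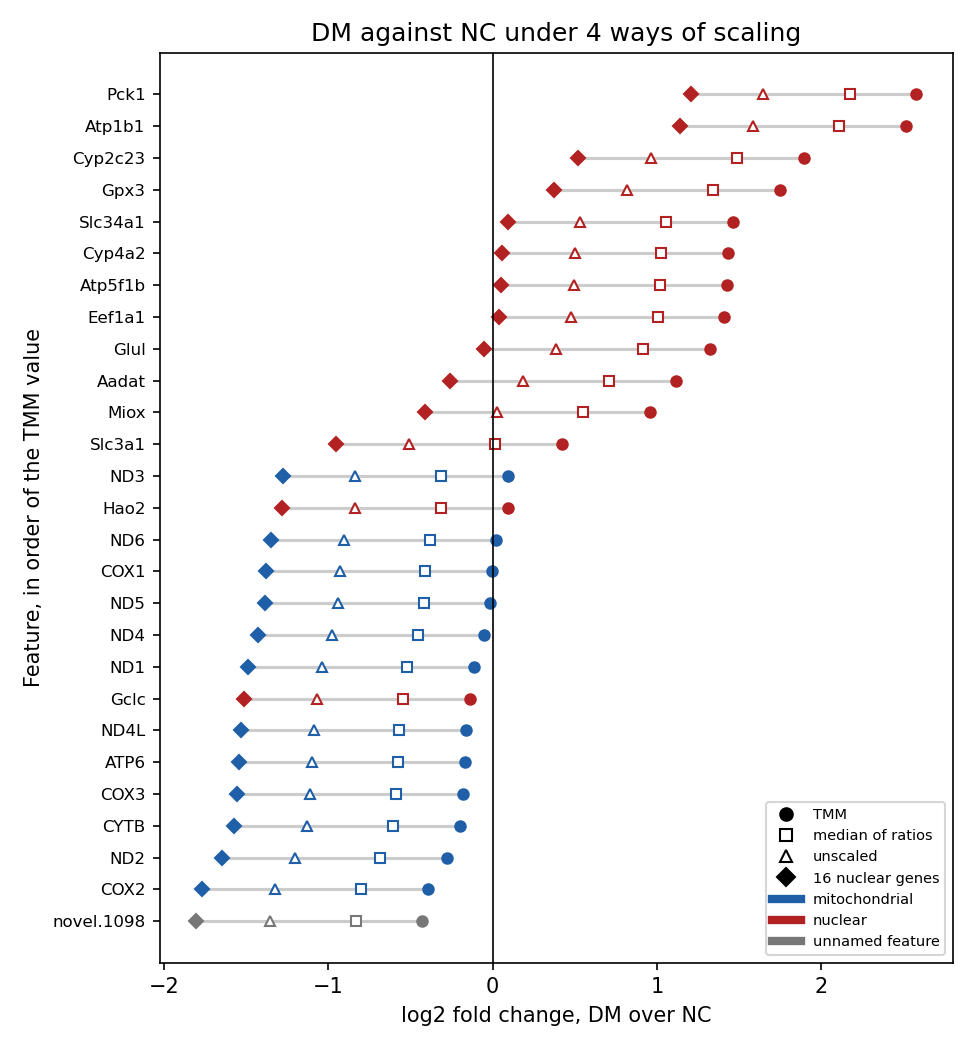
Log2 fold change of DM over NC (x axis) for 27 features (y axis), with a marker for each of 4 scalings and a colour for mitochondrial genes, nuclear genes and the unnamed feature. Pck1, Atp1b1, Cyp2c23 and Gpx3 lie above 0 and pass the threshold under every scaling shown. Slc34a1, Cyp4a2, Atp5f1b and Eef1a1 also lie above 0 throughout, but only just with nuclear scaling (0.09, 0.06, 0.05 and 0.04), where they do not pass. Changing the scaling moves all features by about the same distance.

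At the low dose, Gpx3, Pck1 and Cyp2c23 were higher than in untreated diabetic rats, the question being what each dose of flour changed. Gpx3 was at 228858 ± 20040 counts in LP and Pck1 at 161104 ± 8939 (SD, n = 3), against 101885 and 67806 in DM. Cyp2c23 was at 43412 ± 4397 against 29391. Folds over the 4 scalings were 1.99 to 2.61 for Gpx3, 2.11 to 2.77 for Pck1 and 1.31 to 1.72 for Cyp2c23 (edgeR, adjusted p of at most 0.00675). Aadat, an aminotransferase of lysine and kynurenine breakdown, was 1.49 to 1.95 times lower, at 24280 ± 1655 counts against 42113 ± 2249 (adjusted p of at most 1.4e-05 by edgeR). These 4 calls held under each scaling without any single library. Of the antioxidant genes, Gpx3 rose while Gclc fell under TMM (log2 -0.29, SE 0.080, adjusted p = 0.0107 by edgeR), 2 of 2 when adjusted over the list alone. Gclc did not pass with median-of-ratios factors (log2 -0.15, adjusted p = 0.0773 by edgeR). TMM gave 8 changed features (6 higher and 2 lower), median-of-ratios factors 12 (11 and 1), nuclear scaling 15 (5 and 10) and unscaled counts 7 (4 and 3), with a median log2 fold change of 0.10, 0.24, -0.15 and 0.02.

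The medium dose gave higher counts of these 3 genes. Gpx3 was at 257120 ± 28819 counts in MP, Pck1 at 170889 ± 21299 and Cyp2c23 at 49229 ± 4550 (SD, n = 3). Over the scalings, Gpx3 was 1.98 to 2.52 times higher than in DM, Pck1 1.98 to 2.52 times and Cyp2c23 1.31 to 1.68 times (edgeR, adjusted p of at most 0.00129). Aadat had 34993 ± 2724 counts, lower under 3 scalings and not when unscaled (adjusted p = 0.052 by edgeR). Under TMM, Atp1b1 also fell (log2 -0.49), as did Gclc, Eef1a1, Slc3a1 and Glul, none of them under all 4 scalings. The splits were 13 changed features with TMM (6 higher and 7 lower), 15 with median-of-ratios factors (9 and 6), 14 with nuclear scaling (4 and 10) and 11 unscaled (11 and 0), with medians of -0.01, 0.17, 0.08 and 0.34.

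At the high dose, the 3 genes were close to their counts in DM. Gpx3 was at 106746 ± 6978 counts in HP, Pck1 at 68818 ± 1126 and Cyp2c23 at 30572 ± 4049 (SD, n = 3). In edgeR against DM, Gpx3, Pck1 and Cyp2c23 fell under TMM (log2 -0.35, -0.39 and -0.37) and turned to 0.07, 0.02 and 0.06 when unscaled. Atp1b1 was lower than in DM under all 4 scalings, by 1.22 to 1.62 times (51789 ± 3223 counts, edgeR, adjusted p of at most 0.0427). ND2, ND5 and ND4L, subunits of respiratory complex I, were higher, by 1.2 to 1.66, 1.33 to 1.83 and 1.21 to 1.66 times (edgeR, adjusted p of at most 0.0367). Of these 4 calls, ND5 alone held under all 4 scalings when any 1 DM library, HP replicate 1 or HP replicate 2 was left out, and ND2, ND5 and ND4L did without HP replicate 3. In a TMM-scaled fit of HP and DM alone, ND5 and Atp1b1 passed (adjusted p of 0.0409 and 0.0128) and ND2 (0.115), ND4L (0.0922), Gpx3 and Pck1 (0.0922 each) did not. Of 10 respiratory chain genes, ND2 and ND5 rose, Atp5f1b fell and 7 did not pass under TMM, with 1 passing when adjusted over the list alone. With nuclear scaling 8 members rose and with unscaled counts 9, and in neither did Atp5f1b pass. TMM gave 11 changed features (3 higher and 8 lower), median-of-ratios factors 9 (3 and 6), nuclear scaling 17 (14 and 3) and unscaled counts 18 (16 and 2), with medians of -0.09, 0.02, 0.26 and 0.30.

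Setting HP against the mean of LP and MP, a comparison chosen after the data were seen, described the difference between doses itself. Gpx3 was 2.02 to 2.85 times lower in HP, Pck1 2.15 to 3.01 times and Cyp2c23 1.35 to 1.91 times, under all 4 scalings (edgeR, adjusted p of at most 0.000762). The phosphate transporter Slc34a1 was 1.14 to 1.59 times lower as well. Gclc, Aadat and Slc3a1, a subunit of the cystine transporter, were higher in HP, by 1.19 to 1.69, 1.38 to 1.94 and 1.2 to 1.69 times (edgeR, adjusted p of at most 0.048). Slc34a1 lost a call without LP replicate 1, MP replicate 2 or HP replicate 1, and Slc3a1 without any LP library, MP replicate 1, or HP replicate 2 or 3. TMM gave 14 changed features (3 higher and 11 lower), median-of-ratios factors 14 (3 and 11), nuclear scaling 23 (18 and 5) and unscaled counts 21 (15 and 6), with medians of -0.01, -0.06, 0.42 and 0.26.

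**Figure D3:**
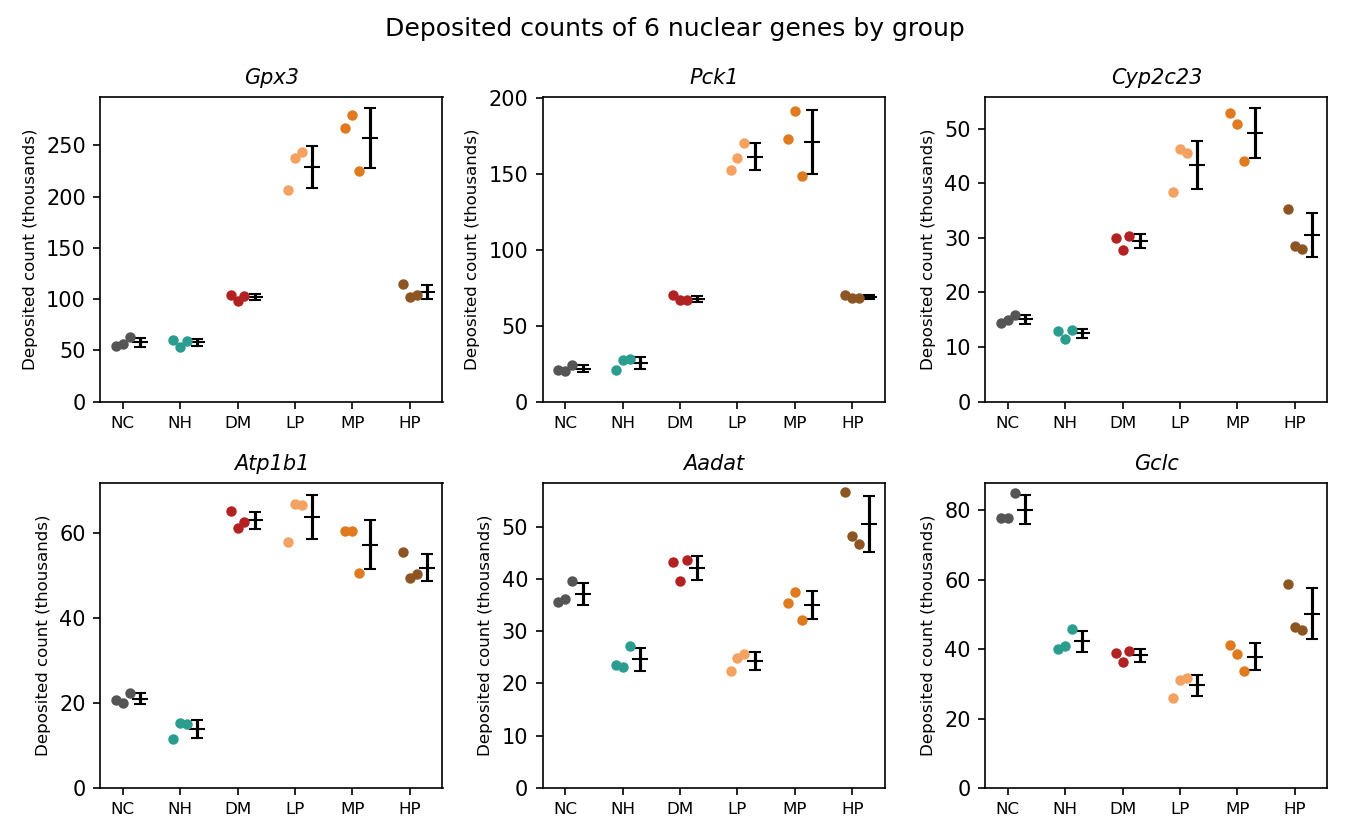
Deposited counts in units of 1000 (y axes, from 0) of Gpx3, Pck1, Cyp2c23, Atp1b1, Aadat and Gclc in the 6 groups (x axes). Dots are libraries and bars the mean ± SD of 3; Gpx3 reaches 228858 and 257120 counts in LP and MP and lies at 101885 and 106746 in DM and HP.

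Taking the 3 doses as one flour-fed group, Gpx3, Pck1 and Cyp2c23 were higher than in DM and Aadat was lower under all 4 scalings. Folds were 1.54 to 1.81 for Gpx3, 1.56 to 1.82 for Pck1 and 1.17 to 1.37 for Cyp2c23, and Aadat was 1.2 to 1.41 times lower (edgeR, adjusted p of at most 0.0262). The high dose alone did not raise Gpx3, Pck1 or Cyp2c23 over DM under TMM. Exact permutation over the 220 splits of the TMM-scaled counts gave p = 0.186 for Gpx3, 0.2 for Pck1, 0.445 for Cyp2c23 and 0.0227 for Aadat. By this test 4 of the 29 features had p under 0.05 and 0 passed after adjustment. In edgeR, Cyp2c23 lost its call without any 1 DM library, and Aadat without DM replicate 1 or 3. TMM gave 10 changed features (5 higher and 5 lower), median-of-ratios factors 11 (8 and 3), nuclear scaling 11 (4 and 7) and unscaled counts 10 (9 and 1), with medians of 0.00, 0.15, 0.07 and 0.23. Along the dose in g per kg, Atp1b1 had a downward slope under all 4 scalings. Under TMM it was -0.20 (SE 0.039) in log2 count per g per kg (edgeR, adjusted p = 0.00568). The slope did not hold under all 4 scalings when any 1 DM or HP library was left out. In all, TMM gave 4 slopes (1 upward and 3 downward, the upward one being ND5 with an adjusted p of 0.0467, and 0.0682 with the replicate number as a block), median-of-ratios factors 3 (0 and 3), nuclear scaling 13 (11 and 2) and unscaled counts 15 (13 and 2).

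In healthy rats, flour went with lower counts of several nuclear genes. Gclc was at 42200 ± 3019 counts in NH against 80198 ± 4145 in NC, and glutamine synthetase, Glul, at 15451 ± 2712 against 28893 ± 3420 (SD, n = 3). Under all 4 scalings, Gclc was 1.44 to 1.9 times lower, Glul 1.43 to 1.87, Eef1a1 1.25 to 1.64, Atp1b1 1.16 to 1.51, the peroxisomal oxidase Hao2 1.14 to 1.49 and Aadat 1.14 to 1.51 times lower (edgeR, adjusted p of at most 0.0265). ND5 and ND4 were higher, by 1.45 to 1.94 and 1.43 to 1.9 times (edgeR, adjusted p of at most 0.0117). Gpx3 (57877 ± 3696 against 57869 ± 4365 counts) and Pck1 (25516 ± 4058 against 21651 ± 2278) did not pass under TMM or unscaled. They were higher with median-of-ratios factors (log2 0.32 for Gpx3 and 0.54 for Pck1) and with nuclear scaling (log2 0.41 and 0.63; edgeR, adjusted p of at most 0.00796). Without NH replicate 1, Pck1 was higher under all 4 scalings. Of 10 respiratory chain genes, 4 rose under TMM (COX1, ND1, ND5 and ND4) and 6 did not pass, with 2 passing when adjusted over the list alone. With median-of-ratios factors and with nuclear scaling 8 rose, and with unscaled counts 2 rose. Without NH replicate 1 neither ND5 nor ND4 held, ND4 was lost without NC replicate 3, and Aadat was lost without NC replicate 1 or 2 or NH replicate 2 or 3. TMM gave 15 changed features (6 higher and 9 lower), median-of-ratios factors 21 (14 and 7), nuclear scaling 23 (16 and 7) and unscaled counts 11 (2 and 9), with medians of -0.02, 0.28, 0.38 and -0.03.

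The effect of the high dose differed between diabetic and healthy rats for Gclc. The gene was lower in NH than in NC and was not lower in HP (50245 ± 7321 counts) than in DM (38215 ± 1793) under any scaling at the threshold. It was higher in HP with nuclear scaling (log2 0.35, adjusted p = 0.00771 by edgeR) and unscaled (0.39, adjusted p = 0.0111). The difference between the effects, HP over DM minus NH over NC, was 0.88 in log2 under TMM (SE 0.11, adjusted p = 2.88e-05 by edgeR) and 0.70 to 1.32 over the 4 scalings. It was the single call under TMM, where 8 features had an unadjusted p under 0.05. Median-of-ratios factors gave 5 calls (1 higher and 4 lower), nuclear scaling 9 (5 and 4) and unscaled counts 7 (7 and 0), with medians of -0.24, -0.06 and 0.39 against -0.05 under TMM.

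The last comparison asked whether features that differed in diabetes moved back with flour. Across the 29 features, which are not independent replicates, the log2 fold changes of HP over DM and of DM over NC had r = -0.863. The shared DM libraries alone gave a median r of -0.58 in simulated unchanged groups (95% of values from -0.971 to 0.667), a range that holds the observed r. The r was 0.408 for LP and 0.0424 for MP, also inside their simulated ranges (-0.972 to 0.639 and -0.972 to 0.641). Over the 16 nuclear genes alone, r was -0.813 for HP (simulated -0.979 to 0.736), 0.387 for LP (-0.978 to 0.748) and 0.319 for MP (-0.975 to 0.744). The simulated groups differed by noise alone, unlike DM and NC, so these ranges of r cannot decide whether features moved back. Covariances over the 29 features were -0.274 for HP (simulated mean -0.00838), 0.17 for LP (-0.00883) and 0.0171 for MP (-0.00869). For HP the simulated mean was small beside the observed value, so shared noise of that size accounted for little of that covariance. The shared calls counted next are those under TMM. In HP, 8 features were higher in DM and then lower, where independent lists would share 3.86. All 8 were nuclear genes, and over the 16 nuclear genes independent lists would share 7. Nuclear genes lower in HP than in DM numbered 8 under TMM, 6 with median-of-ratios factors, 3 with nuclear scaling and 2 unscaled. Also in HP, 1 feature, ND2, was lower in DM and then higher (0.207 expected over all features). Under all 4 scalings, Atp1b1 was higher in DM and then lower in HP, and ND2 the other way round. The HP call of Atp1b1 under all 4 scalings was lost without any 1 DM or HP library. That of ND2 was lost without any of these libraries except HP replicate 3. In MP, 6 features were higher and then lower (3.38 expected over all features and 6.12 over nuclear genes) and 4 were higher in both (2.9 and 3.5 expected). In LP, 4 were higher in both (2.9 and 3.5 expected) and 1 was higher and then lower (0.966 and 1.75 expected). The 3 DM libraries could not be split into parts of at least 2, so whether features moved back stays open.

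The unnamed feature lay on chromosome 20, plus strand, at 19483978 to 19485846 in the deposited positions, and is described in the table as similar to chain 4 of the NADH dehydrogenase. It had 106165 ± 11015 counts in NC, 113373 ± 38271 in NH, 41460 ± 12259 in DM, 39925 ± 16692 in LP, 63007 ± 23051 in MP and 77932 ± 29062 in HP (SD, n = 3). Under TMM it passed in no comparison. It was lower in DM than in NC with median-of-ratios factors (log2 -0.83), unscaled (-1.36) and with nuclear scaling (-1.80). In the same positions, Gpx3 lies on chromosome 10 (40247436 to 40255422), Pck1 on chromosome 3 (171213936 to 171219871) and Gclc on chromosome 8 (85059051 to 85097468). Their identifiers in the table are ENSRNOG00000052564, ENSRNOG00000028616 and ENSRNOG00000006302.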

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

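The effect of the high dose on Gclc differed between diabetic and healthy rats, and the difference itself was tested. The difference in log2 fold change was 0.88 (SE 0.11, adjusted p = 2.88e-05 by edgeR under TMM). Mean counts were 80198 in NC, 42200 in NH, 38215 in DM and 50245 in HP (n = 3 each). The call held under all 4 scalings and without any single library. Of 100 drawn splits of the 12 libraries into the 4 groups, the real one included, 10 gave at least the 1 called feature of the real grouping, so chance is not excluded for that number. The highest other split gave 14 calls, many times the real number. Splits of this kind mix diabetic with healthy libraries, whose mitochondrial to nuclear ratios lie apart. Whether this gave the higher counts was not tested.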

How the results depend on the processing

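The scalings other than TMM, DESeq2, limma on scaled counts, the other forms of the mitochondrial ratio and the comparison of HP with LP and MP were chosen after the data were seen; the remaining alternatives were planned. Direction held for every called gene under limma, the restricted fits, the block, the rank slope and all fits without a library. Of the single-gene results compared, 1 call no longer passed under limma with either pseudocount. Over all fits without a library, 122 single-gene results no longer passed and 544 were the same. In the restricted fits, 13 no longer passed, 6 passed newly and 70 were the same. With nuclear scaling, values in DM against NC reversed for Glul (-0.052), Aadat (-0.26), Miox (-0.41), Slc3a1 (-0.95), Hao2 (-1.28) and ND6 (-1.35), for ND4L in LP (-0.012), for Cyp2c23 (0.011), Cyp4a2 (0.012) and Gpx3 (0.022) in HP against DM, for Cyp2c23 in NH (0.14), and for Eef1a1 (0.021), Atp5f1b (0.022) and COX2 (0.30) in HP against LP and MP. Unscaled counts reversed Slc3a1 (-0.51), Hao2 (-0.84) and ND6 (-0.90) in DM against NC, Gclc in the pooled doses (0.0029), Pck1 (0.021), Cyp4a2 (0.056), Cyp2c23 (0.057) and Gpx3 (0.067) in HP against DM, and COX2 (0.14) in HP against LP and MP. Median-of-ratios factors and DESeq2 reversed Hao2 (-0.31 with both), ND6 (-0.38 with both) and Cyp2c23 in NH (0.046 with both). A scaling adds nearly the same shift to all features of a comparison, which by construction turns those whose value is smaller than an opposite shift. In DM against NC these were not only values near 0. Under TMM, Glul was 2.5 times higher (log2 1.32) and Aadat 2.16 times higher (log2 1.11), and both turned with nuclear scaling.

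Called features in DM against NC rose from 16 to 27 with DESeq2 and with median-of-ratios factors and to 26 unscaled. In LP they rose from 8 to 14 with DESeq2, 15 with nuclear scaling and 14 in a fit of LP and DM alone. In HP against DM they went from 11 to 17 with nuclear scaling, 18 unscaled and 5 in a fit of these groups alone. NH against NC gave 23 in place of 15 with nuclear scaling, and HP against LP and MP 23 in place of 14 with nuclear scaling and 9 with those groups alone. The difference of high-dose effects gave 7 calls with DESeq2, 5 with median-of-ratios factors, 9 with nuclear scaling, 7 unscaled and 2 in a restricted fit, in place of 1. The dose slope gave 7 with DESeq2, 13 with nuclear scaling and 15 unscaled, in place of 4. The cause was not tested for the restricted fits, in which fewer libraries estimate the spread.

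The log2 difference of the mitochondrial ratio moved from -1.47 to -1.33 in DM against NC without Gpx3 and Pck1. In LP against DM it moved from -0.46 to -0.15 without these genes and to -0.19 with geometric means, and in MP it reversed from -0.16 to 0.18 and 0.12. Without a library in turn, the calls ranged from 14 to 16 in DM against NC, 5 to 7 in LP, 6 to 13 in MP, 4 to 16 in HP against DM, 11 to 16 in NH, 10 to 16 in HP against LP and MP, 3 to 11 in the pooled doses, 2 to 8 for the slope and 1 to 3 for the difference of effects. The log2 ratio ranged from -1.51 to -1.43 in DM against NC, -0.50 to -0.43 in LP, -0.21 to -0.08 in MP, 0.27 to 0.52 in HP, 0.42 to 0.59 in NH and -0.17 to -0.01 in the pooled doses.

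With the replicate number as a block, MP against DM, whose numbers go together, gave 15 calls in place of 13, the difference of effects gave 3 calls in place of 1, and of the single-gene results compared 90 were the same, 1 passed newly (CYTB in DM against NC) and 1 no longer passed (the slope of ND5). Depth is unknown, so no limit of detection can be given.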

Other observations

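All tests in this part were chosen after the results were seen, except the splits of the samples for the planned comparisons. Gclc, Aadat, Slc3a1 and Glul moved against Gpx3, Pck1 and Cyp2c23 over the doses. Relative to the geometric mean of the 16 nuclear genes, LP and MP libraries were lower than DM and HP libraries by a mean log2 of -0.58 for Gclc, -0.85 for Aadat, -0.60 for Slc3a1 and -0.47 for Glul, with no overlap between the 6 libraries on each side. Gpx3, Pck1 and Cyp2c23 were higher in LP and MP than in DM and HP, without overlap, by 1.03, 1.09 and 0.44. The grouping of the doses and the genes listed were picked because they separated, so the separation is described and not tested. These values are relative to one another, since the 16 genes set the scale.

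For the lower mitochondrial to nuclear ratio in DM, the values argue against some of the technical explanations examined and leave others open. A difference in sequencing depth moves every feature by 1 factor and leaves the ratio at 0, whereas the log2 difference was -1.47 (SE 0.058). The higher counts of Gpx3 and Pck1 were not the whole of it, since -1.33 (SE 0.058) remained without them. A lower yield of mitochondrial transcripts as a class in the DM libraries cannot be told apart from diabetes. The 12 mitochondrial genes moved nearly as 1 block, with 1 of them more than 3 SE from their median log2 fold change, and RNA quality is not recorded. An effect of diabetes stays open as well. So does an unrecorded batch that set DM apart from NC, which was not tested because the labels give no batch. The nuclear genes compared are those that made a short list of abundant transcripts, and the bearing of that choice on the ratio was not tested.

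The rise of Gpx3, Pck1 and Cyp2c23 at the low and medium dose and not at the high dose is not explained by depth or scaling. The mean log2 count of the 3 genes less that of the other 13 nuclear genes was higher by 1.049 (SE 0.0407) in LP and MP than in DM and HP. A factor that scales a whole library cannot move this difference. The genes and the grouping were picked because they separated, and Gclc, Aadat, Slc3a1 and Glul among the 13 moved the other way. The size of the value and its SE are therefore descriptive. An unrecorded batch that set LP and MP apart from DM and HP cannot be told apart from the dose, because the labels give no batch, and 5 of the other 13 nuclear genes also separated these libraries. A dose response that is not monotone may equally be the source, as a hypothesis that these data do not test further.

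The unnamed feature on chromosome 20 fell with the mitochondrial genes in DM against NC under the 3 scalings other than TMM, and under TMM it passed in no comparison. Its log2 fold change was -0.83 with median-of-ratios factors (adjusted p = 0.0228 by edgeR) and -1.36 unscaled (adjusted p = 0.000816 by edgeR). With nuclear scaling, its log2 fold change of DM over NC was -1.80, beside a median of -1.51 for the mitochondrial genes, while in HP against DM and in NH against NC it did not pass (adjusted p of 0.065 and 0.22 by edgeR). Under that scaling it was higher in HP than in the mean of LP and MP (log2 0.80, adjusted p = 0.032 by edgeR). Its dose slope was also upward (0.25 per g per kg, adjusted p = 0.033 by edgeR). Unscaled, it was higher in HP than in DM (log2 0.91, adjusted p = 0.028 by edgeR). Reads of mitochondrial ND4 RNA counted at a nuclear copy are a candidate source. The median count over the 18 libraries was 61415 for this feature and 40993 for ND4. Deviations from the group means of this feature and of ND4 over the 18 libraries had Pearson's r = 0.381 (permutation p = 0.233, adjusted over both coefficients 0.259) and Spearman's rho = 0.34 (permutation p = 0.259, adjusted 0.259), and r = 0.0866 without the 2 libraries farthest from the median of ND4. The test leaves that source open, with 3 libraries per group, and no biological explanation was tested.

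Other splits of the same samples bear on the counts of called features. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real grouping was the 1 of 10 with the most calls in each case, with 16 for DM against NC, 8 for LP, 13 for MP, 11 for HP against DM and 15 for NH against NC, and the highest other split gave 0 in each. For the pooled doses, 2 of 100 drawn splits gave at least the real 10 calls (highest other 12), and for the dose slope 4 of 100 gave at least the real 4 (highest other 10). Both shares are under 0.05 in the fit without a block, by a margin too small for 100 drawn splits to exclude chance. Of the single features of the pooled doses, 0 passed exact permutation after adjustment (4 with an unadjusted p under 0.05). The counts fell to 3 for the pooled doses and 2 for the slope when 1 library was left out, and with the replicate number as a block the slope gave 3 calls. For the difference of the high-dose effects, 10 of 100 splits gave at least the real 1 call (highest other 14), and chance is not excluded. For HP against LP and MP, 4 of 100 splits gave at least the real 14 calls (highest other 14), but this comparison was picked from the pattern seen, so its splits cannot exclude chance. The splits with 10 slopes and with 14 differences of effects gave counts well above the real numbers. Which libraries those splits set apart was not examined, so a structure of the samples as their source was not tested.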
